A study of Mus musculus with 6 samples.

How the data were processed

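Lung endothelial cells of Dnmt3a knockout and wild-type mice were sorted by flow cytometry, and their DNA was measured by tagmentation-based whole-genome bisulfite sequencing, per the labels' protocols. Each sample used 30 ng of DNA and 3 libraries, read as paired ends of 100 bases, per the labels' protocols. Reads were aligned with BWA 0.7.8 to mm10, per the submitters' processing notes. The deposited table holds a fraction between 0 and 1, the methylation level, for each 1 kb tile and sample, per the file headers. How methylation was called, whether levels were smoothed, which coverage filter was used and how tiles were chosen are not given in the sources used here. The table has 1954255 tiles on chromosomes 1 to 19, 0 missing values, 0 values of exactly 0 and 8 of exactly 1. It gives no read counts, so depth is unknown, no confidence interval or detection floor was computed, and a shallow sample cannot be told from a deep one. Neighbouring tiles shared noise: deviations from the group mean correlated at r = 0.531 to 0.553 between adjacent tiles across tiles, which are not independent replicates. Levels of samples correlated across tiles at r = 0.914 to 0.925 within a group and 0.839 to 0.854 between groups.

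The fractions were multiplied to percent. Samples were grouped as KO or WT by the genotype in their labels, 3 in each group, and all 6 entered every test. The design fixed before the data were examined foresaw a logistic model of read counts. Because the table holds levels only, the alternative written there for that case was used: limma 3.58.1 (R 4.3.3), with a trend of the variance on the mean level, on the level of each region, with Benjamini-Hochberg adjustment over the regions of one kind. Tiles and gene ends were called at an adjusted p under 0.05 and a difference of at least 10 points, gene bodies at 5 points. Called tiles of one direction with a gap of at most 1 kb were merged. Single values, such as the mean level of a sample over a class, were compared with a two-sided exact permutation test, whose smallest p is 0.10 with 3 against 3 samples. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

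Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names. The table has no strand, exons or sequence, so promoters, exons, introns, untranslated regions, CpG islands and the bases around a CpG were not analysed here. In place of promoters, the 2 ends of each protein-coding gene were averaged over tiles that overlap 1000 bp on either side, and the end with the lower mean level over all 6 samples was kept, for 19921 of 20665 genes. Without strand, a gene end can be the start or the far end of its gene, and it cannot be read as a promoter. Gene bodies were the mean of tiles fully inside a gene and at least 1000 bp from its ends, with at least 3 tiles, for 15364 genes, and they can overlap other genes. Tiles were also grouped by feature, by mean level over all samples (limits at 10, 50 and 80%) and by distance to the nearest tile under 10%. The location of calls was compared with tiles whose mean level leaves room for a change of 10 points, by 1000 circular shifts of the tile order.

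A set of 17 gene lists with 439 genes was fixed before the data were examined, and 438 of the symbols were in the gene table. They held pan-endothelial, lung capillary, arterial, venous and lymphatic markers, VEGF and angiogenesis genes, TGF-beta and BMP genes, endothelial transcription factors, developmental regulators, germline genes, imprinted genes, genes of DNA methylation, markers of leukocytes, epithelium, mesenchyme and erythroid cells, and housekeeping genes. The sort for endothelial cells was meant to exclude leukocytes, epithelium, mesenchyme and erythroid cells. The lung capillary and epithelial lists share Rtkn2, and the lists of endothelial transcription factors and imprinted genes share Peg3. The median difference of a list was compared with 10000 random lists of the same size matched on mean level and number of tiles, with adjustment over 34 tests. The design foresaw matching on CpG number, which the deposited table does not give, so number of tiles was used instead. Distance to a valley was not matched. Families of genes picked by symbol after the data were seen made 26 more tests.

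The genes named followed a rule fixed before the data were examined. It took the 10 regions in each direction with the smallest p of their best tile, at least 2 called tiles and no overlap between the groups, the 6 gene ends in each direction with the largest difference and no overlap, and up to 3 called genes of each list with the smallest p. The gene bodies with the largest differences and the longest region were added after the values were seen. Of the genes these rules picked, 2 are not reported here. The tests were checked on 100000 simulated tiles with the real levels and spread, in which 3000 each were lowered by 10, 20 and 30 points. Of these, 24.3, 83.6 and 97.8% were recovered, and 3.44% of calls were false. In a simulation with no change, 0 tiles were called. Noise was drawn separately for each simulated tile, whereas neighbouring real tiles share noise, and only tiles above a set WT level were lowered. These shares may thus differ for the real calls.

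The alternatives tried were no minimum difference, a minimum at 2 times the main one, an adjusted p under 0.01, the logit of the level, replicate numbers as a block, leaving out each sample, gene ends within 500 bp and level classes by the WT samples. Chosen after seeing the data were limma without the trend, centring each sample on its median, scaling to one mean level, other definitions of a gene end, the median over tiles, and valleys by the WT samples.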

Results

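DNA methylation was measured by whole-genome bisulfite sequencing, which reads cytosine methylation across the genome, in endothelial cells sorted from mouse lung. The comparison was between 3 samples from mice lacking Dnmt3a, a de novo DNA methyltransferase, and 3 samples from wild-type mice, called KO and WT here. It asks where methylation in lung endothelium depends on this enzyme. Each sample had a methylation level, in percent, for 1954255 tiles of 1 kb on chromosomes 1 to 19 (mm10), with no missing value. The values come without read counts, so the depth behind each level is unknown and no counting interval is given. Errors are standard deviations over the samples of a group, n = 3 in each. The labels do not say whether the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

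The span of Dnmt3a itself (chromosome 12, 3801559 to 3914443) had a mean level of 50.3% ± 0.983 in KO and 65.6% ± 0.620 in WT (SD, n = 3). The values were 49.6, 50.002 and 51.4% in KO replicates 1 to 3 and 66.3, 65.2 and 65.3% in WT. Of its 113 measured tiles, 63 fell in KO and 0 were called higher (limma). The tile from 3897001 to 3898000 was higher by 9.07 points at an adjusted p of 0.0146 and missed only the 10-point minimum; it is the 1 tile that was higher at an unadjusted p under 0.05. Levels do not show which part of the gene was deleted, so this span does not check the genotype labels.

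Methylation was lower in KO across the genome. The mean level over tiles was 63.7% ± 0.140 in KO and 69.0% ± 0.451 in WT, a difference of -5.36 points (n = 3 per group, two-sided exact permutation test, p = 0.10, the smallest that 3 against 3 samples allow). The KO samples lay at 63.5, 63.7 and 63.8%, all below the WT samples at 69.5, 68.8 and 68.7%. Every one of the 19 chromosomes had a lower mean in KO, from -4.84 points on chromosome 1 to -6.59 on chromosome 11. Highly methylated tiles, at 80% or more, numbered 267117 ± 4323 in KO against 498780 ± 25396 in WT. Tiles from 10 to 50% numbered 262842 ± 5522 against 155097 ± 6075, and tiles under 10% numbered 41198 ± 602 against 27286 ± 258.

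The differences ran almost entirely in 1 direction. With limma at an adjusted p under 0.05 and a difference of at least 10 points, 316257 tiles fell in KO and 1555 rose, so 99.5% of calls were losses. After each sample was centred on its median level, 129769 tiles were lower and 18197 higher, 87.7% losses. After scaling to one mean level the split was 128517 to 30656, 80.7% losses. Tiles called lower had a median difference of -15.6 points, and 2584 of them lost 50 points or more. In 1247 tiles the mean was at 50% or more in WT and under 10% in KO, and 0 tiles had the reverse. All 3 KO samples lay below all 3 WT samples in 31.6% of tiles and above them in 1.54%. Chance gives 5% for each of these orders, 10% for both.

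**Figure D1:**
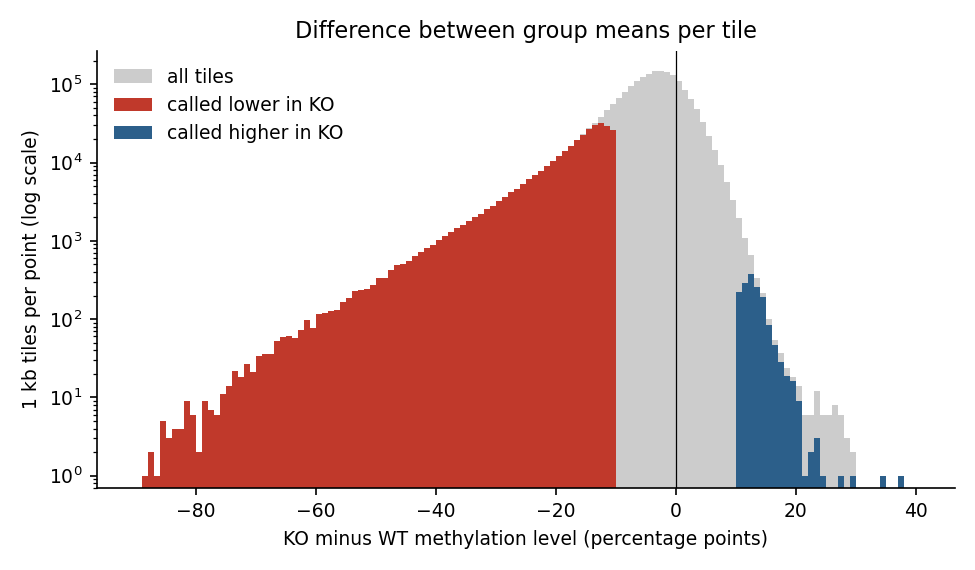
Number of 1 kb tiles (log axis) by the difference between the KO and WT group means, in percentage points, with called tiles in colour. The 316257 tiles called lower in KO reach beyond -80 points, while the 1555 called higher have a median of 12.7 points.

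Losses were larger around genes than between them and were largest beside unmethylated valleys. Mean levels differed by -6.33 points in tiles at the ends of protein-coding genes, by -6.26 inside them, by -5.84 in other annotated genes and by -4.33 outside genes (exact permutation p = 0.10 in each class, n = 3 per group). Tiles at gene ends had an odds ratio of 1.61 for a call of lower methylation and tiles outside genes 0.567 (permutation by circular shifts of the tile order, p = 0.002 for both, the smallest that the shifts can give). By mean level over all samples, tiles at 10 to 50% differed by -10.8 points, with 38.7% of them called lower. Tiles at 50 to 80% differed by -5.08 points and tiles at 80% and over by -3.89. These classes depend on which samples define them: by the WT mean alone, tiles at 10 to 50% differed by -6.46 points and tiles at 80% and over by -6.50.

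Valleys were tiles under 10% in the mean of all samples. Tiles 1 kb from a valley were at 36.1% ± 0.452 in KO and 49.4% ± 0.458 in WT, a difference of -13.3 points, and 49.1% of them were called lower. The difference was -11.0 points at 2 to 3 kb, -8.03 at 6 to 10 kb, -6.51 at 21 to 50 kb and -2.36 beyond 200 kb, where 4.58% of tiles were called lower. Each of these differences had an exact permutation p of 0.10 (n = 3 per group).

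**Figure D2:**
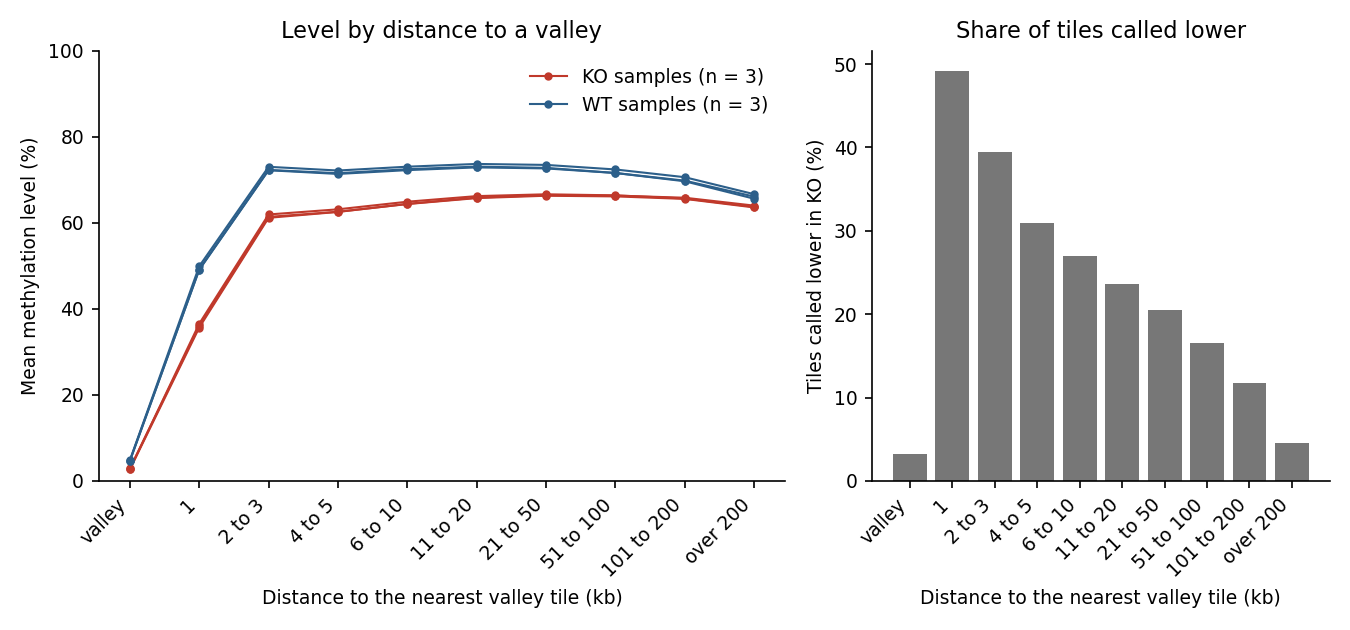
Left, mean methylation level (%) of each KO and WT sample (lines with points) by distance in kb to the nearest valley tile. Right, share of tiles called lower in KO (%, bars); the share is 49.1% at 1 kb and 4.58% beyond 200 kb.

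Adjacent called tiles merged to 109779 regions of lower methylation, which covered 343 Mb, and 4151 of them held at least 10 called tiles. The levels given for a region are means over its called tiles. Of the 10 regions with the smallest p, a 32 kb region, of which 27.9 kb lay in the homeobox gene Hoxb3 and which reached Hoxb4 and Hoxb2, was at 1.74% ± 0.231 in KO and 59.7% ± 0.795 in WT (chromosome 11, 96320001 to 96352000). An 18 kb region at one end of Nr2f2, which encodes COUP-TFII, a transcription factor of venous identity, was at 21.3% ± 0.284 in KO and 57.7% ± 1.70 in WT (chromosome 7, 70362001 to 70380000). Of it, 4.75 kb lay in Nr2f2 and 14.6 kb in the non-coding gene B130024G19Rik. A 21 kb region beside the homeobox gene Hlx, with 1.86 kb inside it, was at 19.9% ± 0.218 and 56.5% ± 1.23 (chromosome 1, 184708001 to 184729000). Of this region, 6.49 kb lay in the non-coding gene 4930488B22Rik. The gene end of Hlx itself was at 1.40% ± 1.396 and 1.48% ± 0.766 (limma, adjusted p = 0.945). A region of 90 kb inside Nfix, a nuclear factor I gene, held 82 called tiles and was at 33.0% ± 0.478 in KO and 64.2% ± 1.25 in WT (chromosome 8, 84709001 to 84799000).

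A shorter region lay in Bmp7, a bone morphogenetic protein (chromosome 2, 172935001 to 172939000), at 1.46% ± 0.155 in KO and 58.5% ± 0.617 in WT. Another, with 1.91 of its 8 kb in Skida1 (chromosome 2, 18038001 to 18046000), was at 3.94% ± 1.30 and 68.8% ± 2.56. A region inside Nr5a2, an orphan nuclear receptor gene (chromosome 1, 136949001 to 136952000), had 2.75% ± 1.14 in KO and 63.0% ± 1.64 in WT. A region of 11 kb, with 2.96 kb in the Wnt receptor gene Fzd7 (chromosome 1, 59484001 to 59495000), had 26.0% ± 0.907 and 62.8% ± 2.92. The other 2 overlapped the ends of genes by less than 1 kb. One met Tnrc18 (chromosome 5, 142823001 to 142827000), at 25.5% ± 3.24 and 68.4% ± 0.997. The other met the non-coding gene Gm35196 (chromosome 14, 61684001 to 61687000), at 1.01% ± 0.495 and 59.5% ± 3.73. The best tile of each of the 10 regions had an adjusted p of 7.36e-11 (limma). The longest region, chosen after its values were seen, ran for 104 kb in Gse1 (chromosome 8, 120246001 to 120350000), at 43.6% ± 0.372 in KO and 73.4% ± 0.316 in WT.

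**Figure D3:**
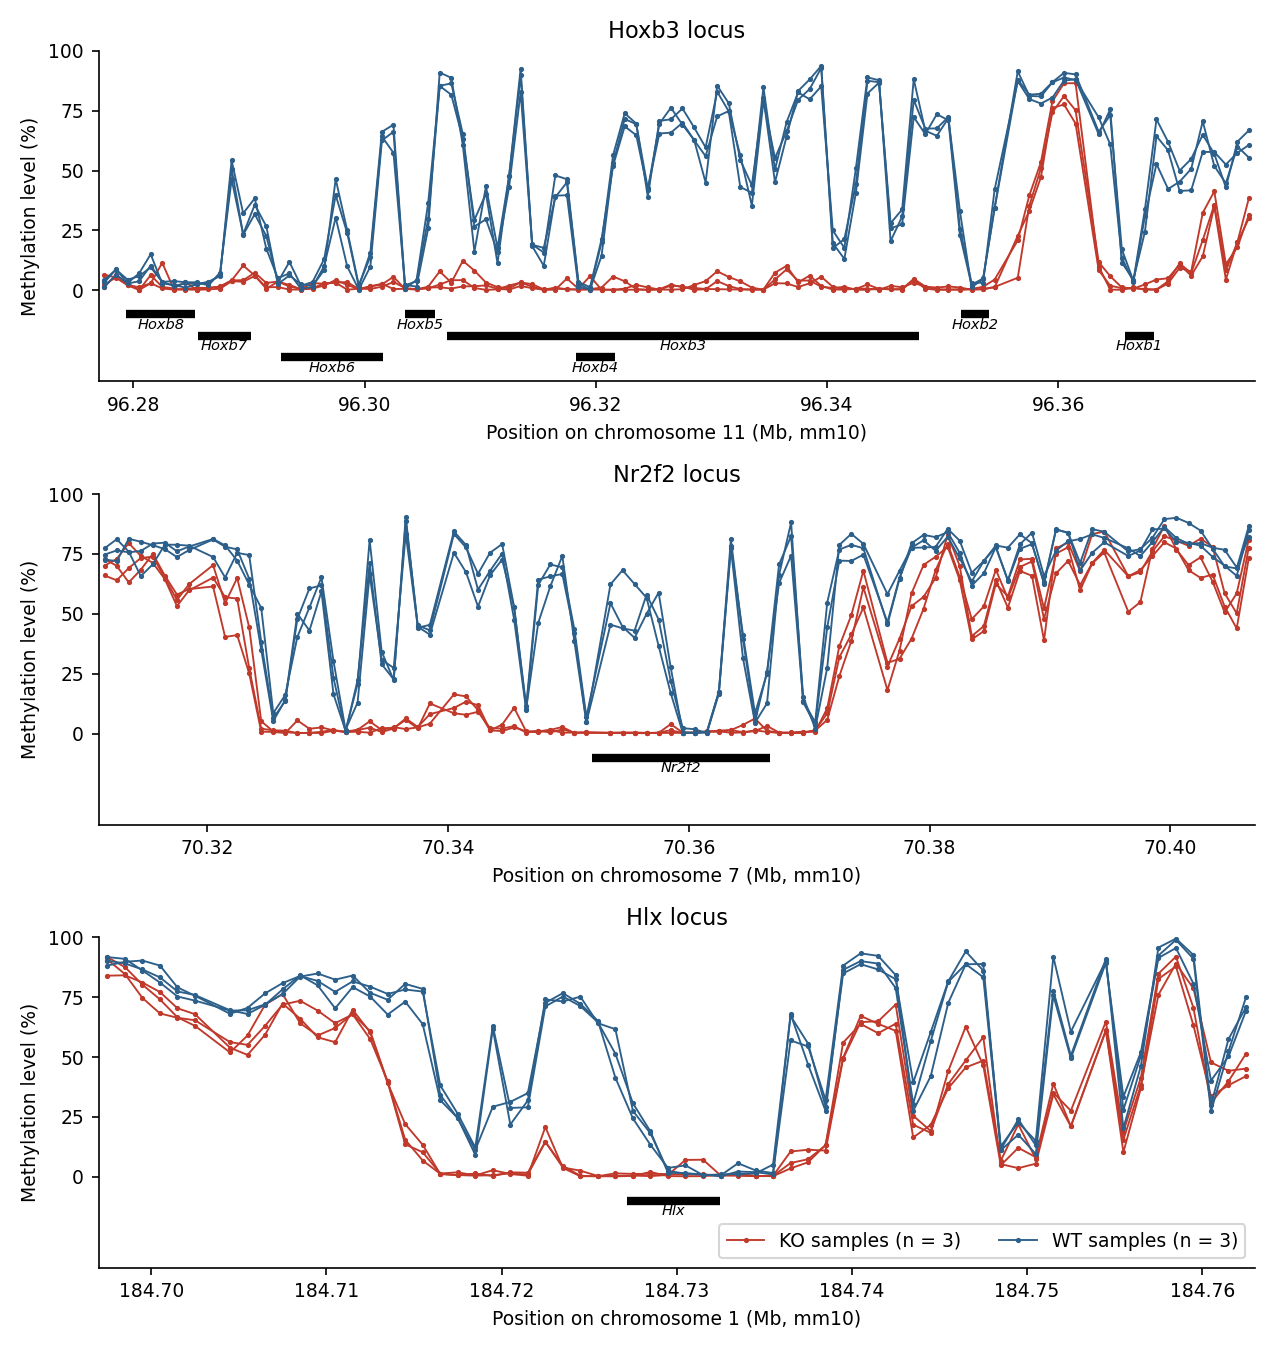
Methylation level (%) of 1 kb tiles (points) in each KO and WT sample (lines) along the Hoxb3, Nr2f2 and Hlx loci, with protein-coding genes as black bars (position in Mb, mm10). The called region from Hoxb4 to Hoxb2 averages 1.74% in KO and 59.7% in WT.

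Gene by gene, 3727 of 19921 gene ends fell and 8 rose, and 8182 of 15364 gene bodies fell and 2 rose (limma, 10 points for ends and 5 for bodies). Without any one sample, 13 to 23 ends and 2 to 11 bodies rose. The median difference was -4.66 points over gene ends and -5.37 over gene bodies. After scaling to one mean level, 2218 gene ends were lower and 133 higher. Of gene bodies, 2646 were then lower and 881 higher, so their share of losses went from 99.98 to 75.02%. The gene ends that fell most were those of Hoxb3 (2.02% ± 0.257 in KO, 59.0% ± 3.93 in WT), the chromatin reader Zmynd8 (13.4% ± 1.79, 69.7% ± 3.17), Mab21l1 (3.37% ± 1.62, 59.0% ± 7.63) and the orphan receptor Nr4a2 (7.81% ± 2.23, 62.5% ± 5.04). Next were the tight junction gene Cldn4 (16.2% ± 1.398, 69.97% ± 0.144) and Fam169a (8.66% ± 1.35, 59.3% ± 6.21). When only 500 bp around the ends were used, the end to keep was chosen anew. For Nr4a2 it was then the other end, at -8.12 points with no call, which does not bear on the end given here. The gene table gives no strand, so none of these ends is shown to be a gene start. Among the largest losses over gene bodies were those in the cytokine receptor kinase gene Jak3 (11.7% ± 1.42 in KO, 67.1% ± 1.81 in WT), Plekhh3 (12.1% ± 2.41, 64.7% ± 2.87) and the T-box gene Tbx2 (1.86% ± 0.837, 54.3% ± 3.53). Others were in Hoxb3 (1.76% ± 0.0645, 51.3% ± 0.667), the Wnt receptor gene Fzd5 (15.7% ± 1.82, 64.8% ± 2.54), Nab2 (2.77% ± 0.652, 49.5% ± 1.47) and Tnfaip2 (17.8% ± 2.77, 63.9% ± 1.80).

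Some genes of the endothelial lists lost methylation, and no member of any of the 17 lists was called higher (limma; 2 of 421 ends and 0 of 319 bodies were higher at an unadjusted p under 0.05). These 2 ends, named after their values were seen, were of Hoxc10 (4.67% ± 1.14 in KO, 2.20% ± 1.40 in WT) and Hoxc13 (6.85% ± 3.17, 3.19% ± 0.0661). Both had an adjusted p under 0.05 in limma (0.0439 and 0.0449) and missed only the 10-point minimum. Of the pan-endothelial markers, 10 of 34 gene ends and 20 of 26 gene bodies fell. They included the VEGF receptor gene Flt1 (end 2.50% ± 0.997 in KO, 25.3% ± 0.405 in WT), endothelial nitric oxide synthase Nos3 (body 58.7% ± 1.82, 78.7% ± 1.999) and the ETS factor Fli1 (body 43.1% ± 0.630, 59.6% ± 1.56). Of the VEGF and angiogenesis genes, 15 of 33 ends and 28 of 31 bodies fell. Among them were Esm1 (body 48.6% ± 0.814, 72.5% ± 0.643) and the feedback regulators Dusp5 (end 0.914% ± 0.0849, 13.7% ± 0.575) and Spry4 (end 1.33% ± 0.478, 13.6% ± 0.286). Of the endothelial transcription factors, 13 of 31 ends and 23 of 27 bodies fell. Nr2f1 was at 8.14% ± 1.70 in KO and 54.0% ± 0.830 in WT over its body. The end of Meox1 was at 16.8% ± 1.72 and 48.0% ± 0.473 and that of Rreb1 at 6.18% ± 1.19 and 26.4% ± 0.136. For each of these 3 lists the counts adjusted over the list alone were equal to those over all genes.

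Members of the vessel type lists fell too. Of the venous markers 8 of 14 ends and 9 of 11 bodies were lower. The end of Nr2f2 was at 0.385% ± 0.0535 in KO and 23.4% ± 1.86 in WT and that of Car8 at 9.81% ± 3.31 and 44.9% ± 3.99. The body of Nrp2 was at 51.3% ± 0.235 and 71.1% ± 0.497. Of the arterial markers 6 of 19 ends and all 16 measured bodies fell. Examples were the connexin gene Gja4 (end 16.9% ± 1.07, 40.9% ± 1.018), the Notch ligand gene Jag2 (body 51.2% ± 0.139, 70.01% ± 0.351) and the netrin receptor gene Unc5b (body 43.1% ± 0.429, 65.5% ± 0.846). Of the lung capillary markers 8 of 18 ends and 12 of 14 bodies fell, with Tbx2 and the end of Nostrin (11.2% ± 1.05, 30.5% ± 2.95) among them. Rtkn2, which the epithelial list also holds, was at 71.3% ± 0.920 and 80.1% ± 0.451 over its body, a call that scaling to one mean level ended (-2.67 points). Of the lymphatic markers 3 of 13 ends and 6 of 10 bodies fell. They included the bodies of Tbx1 (2.86% ± 0.244, 34.6% ± 0.425), the VEGF receptor gene Flt4 (43.2% ± 1.31, 62.1% ± 1.37) and Itga9 (60.6% ± 0.187, 73.6% ± 1.08). Of the TGF-beta and BMP genes 8 of 31 ends and 22 of 25 bodies fell. Smad3 was at 52.5% ± 0.331 and 76.7% ± 0.869 over its body. The end of Snai1 was at 2.31% ± 0.818 and 28.2% ± 3.89 and that of Id2 at 1.34% ± 0.434 and 17.7% ± 2.06. The counts adjusted over the list alone were equal to those over all genes in each of these 5 lists.

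Against random genes matched on level and tile number, 5 of these 8 lists had larger losses at gene ends. The random genes were not matched on distance to a valley. Over tiles the loss went from -13.3 points at 1 kb from a valley to -2.36 beyond 200 kb. Differences from matched lists are thus not told apart from nearness to valleys. The median difference was -11.0 points for venous markers (random lists -4.53, adjusted permutation p = 0.00453), -8.39 for angiogenesis genes (-3.83, 0.00227) and -7.98 for lung capillary markers (-4.32, 0.0310). It was -5.56 for TGF-beta and BMP genes (-3.12, 0.0310) and -4.70 for endothelial transcription factors (-2.38, 0.0243). The median was -5.36 for pan-endothelial (adjusted permutation p = 0.134), -4.57 for arterial (0.167) and -6.75 for lymphatic markers (0.167). Within 500 bp the end to keep was chosen anew, so it can be the other end of a gene. The median of all gene ends went from -4.66 to -3.08 points there, and the medians of matched lists shrank for each of the 8 lists. Medians of the lists themselves were smaller in 7 of the 8. They were -4.48 for venous markers, -2.67 for angiogenesis genes and -4.999 for lung capillary markers. The others were -1.46 for TGF-beta and BMP genes, -1.16 for endothelial transcription factors, -1.71 for pan-endothelial and -2.43 for lymphatic markers. There the arterial list, at -5.25 points, was the only one of the 8 beyond its matched lists (adjusted permutation p = 0.00340). The calls for Flt1 (-0.701), Spry4 (-0.268), Id2 (-1.69), Dusp5 (-2.01), Nr2f2 (-5.02), Nostrin (-6.11), Snai1 (-8.13) and Gja4 (-8.73) ended there. Over gene bodies the medians of endothelial transcription factors (-13.2 points, adjusted permutation p = 0.00272), angiogenesis genes (-12.3, 0.00272) and venous markers (-12.2, 0.0381) exceeded those of matched lists. They did not for arterial (-11.5, 0.174), lymphatic (-12.6, 0.0958), TGF-beta and BMP (-7.68, 0.446), lung capillary (-7.76, 0.803) or pan-endothelial genes (-8.37, 0.924). Centring, which takes -4.89 points off every difference, turned the median over ends to 0.321 for arterial markers and 0.193 for endothelial transcription factors, and left the other 6 lists negative. Scaling to one mean level left these 2 at -4.05 and -4.10.

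**Figure D4:**
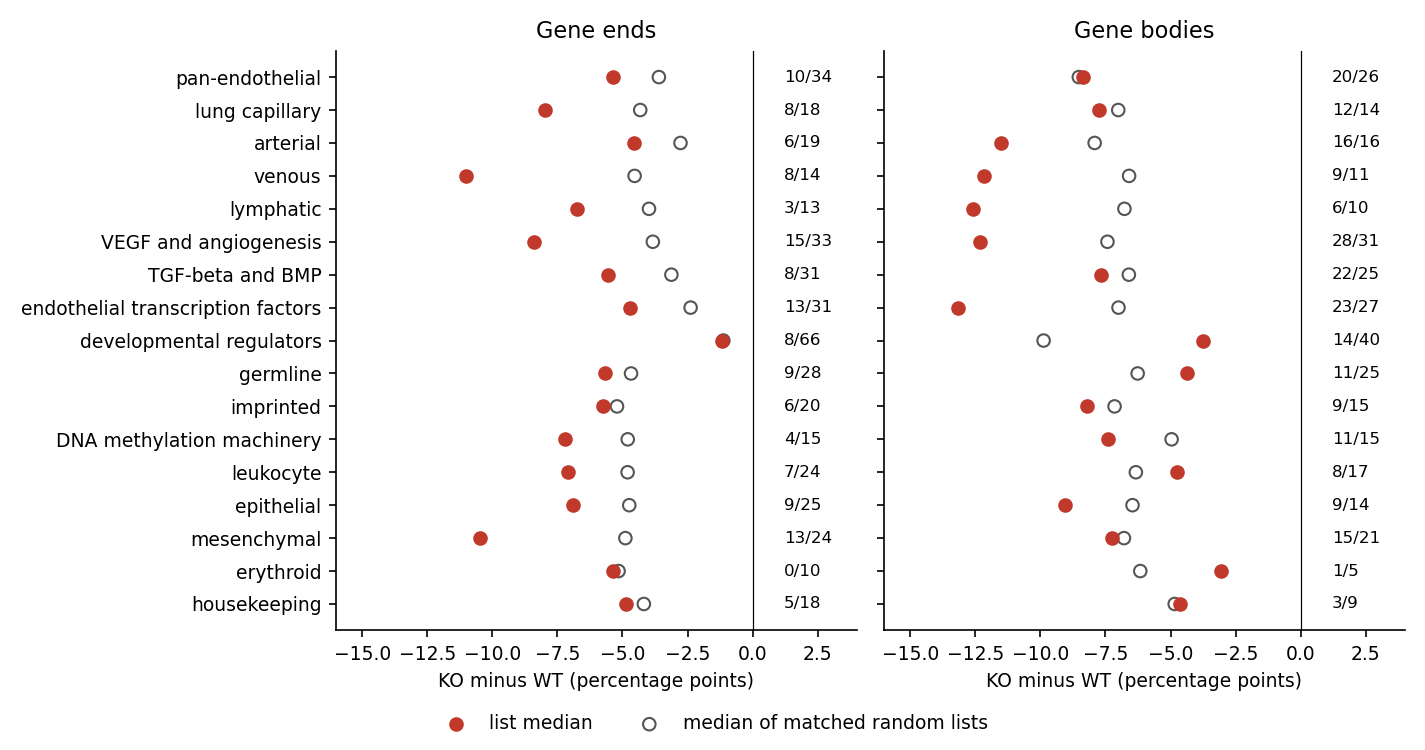
Median KO minus WT difference (percentage points) over the members of each list (filled points) and of matched random lists (open points), for gene ends and gene bodies. Figures at the right of each panel give members called lower over members measured, such as 28 of 31 angiogenesis gene bodies; no member of any list was called higher.

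Developmental regulators were low at gene ends in both groups, at a list mean of 2.45% ± 0.333 in KO and 6.41% ± 0.191 in WT. Of this list 8 of 66 ends and 14 of 40 bodies fell. The list holds neighbouring Hox genes, so its counts and tests may rest on fewer separate loci than members. Its median was -1.18 points at ends, near the -1.12 of matched lists (adjusted permutation p = 0.893). It was -3.76 over bodies, a smaller loss than the -9.88 of matched lists (adjusted permutation p = 0.00227). Both medians turned positive on centring, at 3.71 and 1.13 points, and stayed negative on scaling to one mean level, at -1.005 and -1.57. Centring takes -4.89 points off every difference, so an end under 4.89% in WT turns positive whatever its change. The sign at ends after centring thus cannot be read as a relative gain. The members that fell included the ends of Hoxb1 (1.46% ± 1.06 in KO, 29.3% ± 2.90 in WT) and Hoxb5 (1.44% ± 0.849, 23.0% ± 2.38), whose calls ended within 500 bp at -8.20 and -1.90 points. Of the genes of DNA methylation itself 4 of 15 ends and 11 of 15 bodies fell. They included the ends of Dnmt3b, the other de novo methyltransferase (4.32% ± 1.67, 27.8% ± 0.557), of Tet3, a 5-methylcytosine oxidase (17.3% ± 0.798, 38.4% ± 1.47), and of the methyl-CpG reader Zbtb38 (26.4% ± 5.30, 66.7% ± 1.55). Of imprinted genes 6 of 20 ends and 9 of 15 bodies fell. Examples were the bodies of Plagl1 (47.9% ± 0.397, 71.8% ± 0.598), Igf2r (57.1% ± 0.247, 69.6% ± 1.31) and Inpp5f (67.7% ± 0.450, 78.0% ± 0.588), whose call ended on scaling to one mean level (-4.49 points). Of germline genes, which DNA methylation is known to silence in body cells, 9 of 28 ends and 11 of 25 bodies fell. The body of Dmrtb1 was at 52.0% ± 0.110 and 61.5% ± 0.674 and that of Mael at 68.9% ± 1.07 and 75.2% ± 0.426. Scaling to one mean level ended the calls for Dmrtb1 (-4.92 points) and Mael (-0.483), and centring that for Mael (-1.41). The end of Stk31 was at 59.9% ± 2.79 and 84.9% ± 3.23, but its sign turned, to 3.12 points with no call, when the end was chosen on the WT samples alone.

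Some markers of other lung and blood cells were also lower. Of mesenchymal markers 13 of 24 ends and 15 of 21 bodies were lower, and the median of -10.5 points at ends was beyond matched lists (-4.89, adjusted permutation p = 0.00227). The ends of Mfap4 (17.8% ± 1.51 in KO, 49.2% ± 1.41 in WT), Tbx4 (8.41% ± 1.86, 39.98% ± 4.82) and Tcf21 (1.17% ± 0.527, 17.8% ± 3.77) were among them. Of epithelial markers 9 of 25 ends and 9 of 14 bodies fell. They included Cldn4, the keratin gene Krt8 (end 13.9% ± 2.81, 36.8% ± 2.92) and Hopx (body 56.6% ± 0.210, 69.1% ± 0.603). Of leukocyte markers 7 of 24 ends fell (8 adjusted over the list alone) and 8 of 17 bodies. They included the ends of the B-cell gene Cd79b (43.5% ± 3.52, 66.8% ± 1.71) and the myeloid factor Spi1 (24.8% ± 2.21, 39.9% ± 0.874). The body of Mrc1 was at 68.6% ± 0.817 and 74.1% ± 0.318, a call that ended on centring (-0.693 points) and that scaling to one mean level turned to 0.182 points with no call. Of erythroid markers 0 of 10 ends (3 at an unadjusted p under 0.05 in limma) and 1 of 5 bodies fell, the latter that of Slc4a1 (58.5% ± 1.99, 65.9% ± 2.22), whose call ended on centring (-2.52 points) and on scaling (-2.38). Of housekeeping genes 5 of 18 ends and 3 of 9 bodies fell. Among them, the end of Gapdh was at 7.85% ± 1.75 and 19.8% ± 1.26 and that of Actb at 11.1% ± 2.99 and 22.6% ± 3.16. The call for Actb ended without WT replicate 1 (-9.76 points) and with the end chosen on the WT samples (-9.08), and that for Gapdh within 500 bp (-1.998).

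None of the other list medians stood apart from matched lists. At gene ends they were -7.22 points for genes of DNA methylation (adjusted permutation p = 0.188), -7.09 for leukocyte (0.174) and -6.91 for epithelial markers (0.167), -5.76 for imprinted (0.803), -5.67 for germline (0.579) and -4.86 for housekeeping genes (0.719), and -5.36 for erythroid markers (0.924). Over gene bodies they were -9.05 for epithelial markers (adjusted permutation p = 0.167), -8.21 for imprinted genes (0.719), -7.39 for genes of DNA methylation (0.0958) and -7.26 for mesenchymal markers (0.827). The smallest were -4.73 for leukocyte markers (adjusted permutation p = 0.382), -4.64 for housekeeping (0.899) and -4.38 for germline genes (0.167), and -3.05 for erythroid markers (0.243). Centring and scaling turned these last 4 medians positive, to between 0.160 and 2.68 points, and centring moved the housekeeping ends to 0.0356, where scaling left -3.59. Within 500 bp of the end, the mesenchymal median of -9.10 points stayed beyond matched lists (adjusted permutation p = 0.00850), and the developmental median of -1.09 exceeded the -0.631 of matched lists (0.0295).

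The 1555 tiles that rose formed 1360 regions, of which 179 held at least 2 called tiles and the longest ran for 7 kb. Most of these tiles, 58.0%, lay outside genes (odds ratio 1.71), and 46.8% lay beyond 200 kb from a valley (odds ratio 2.37, permutation by circular shifts, p = 0.002 for both, the smallest possible). The region with the smallest p overlapped the ribosomal RNA pseudogene Rn18s-rs5 by 1.85 kb and the non-coding gene AY036118 by 0.889 kb (chromosome 17, 39842001 to 39849000), at 31.6% ± 4.01 in KO and 14.8% ± 3.10 in WT. Others lay in Lars2, a mitochondrial leucyl-tRNA synthetase gene (chromosome 9, 123461001 to 123463000), at 33.1% ± 3.59 and 18.1% ± 3.09, and in Gphn (chromosome 12, 78350001 to 78352000), at 33.5% ± 1.55 and 18.9% ± 1.997. One lay in Atf2 (chromosome 2, 73867001 to 73869000), at 50.7% ± 6.35 and 31.7% ± 6.15. A region in the potassium channel gene Kcnh6 (chromosome 11, 106031001 to 106033000) was at 52.8% ± 12.7 and 27.8% ± 6.22. One in the pseudogene Anp32b-ps1 (chromosome 4, 143389001 to 143391000) was at 58.9% ± 1.61 and 43.5% ± 3.19. Of the remaining 4, a pair lay on chromosome 6 (3200001 to 3202000, 44.6% ± 3.49 and 28.1% ± 2.63) and chromosome 9 (3258001 to 3261000, 44.6% ± 2.01 and 30.3% ± 4.44). Those left were on chromosome 16 (71212001 to 71215000, 62.0% ± 6.05 and 44.5% ± 3.92) and chromosome 1 (5541001 to 5544000, 69.5% ± 1.75 and 52.6% ± 5.31, with Oprk1 the nearest gene).

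The gene ends that rose were mostly those of tandem gene families. Whether their members share reads was not analysed here. The defensin genes Defb7 (64.5% ± 5.19 in KO, 48.5% ± 5.71 in WT), Defa31 (63.0% ± 1.76, 49.2% ± 10.5) and Defb6 (58.7% ± 3.01, 48.4% ± 1.46) rose. So did the olfactory receptor genes Olfr907 (65.0% ± 4.70, 51.2% ± 1.16) and Olfr775 (58.7% ± 6.82, 46.6% ± 2.45) and the acetylcholine receptor gene Chrna2 (60.4% ± 4.05, 49.0% ± 5.32). Of these 6 calls, 4 ended on leaving out a sample. The call for Defa31 ended on leaving out any sample other than WT replicate 2 (10.7 to 14.4 points, adjusted p from 0.0537 to 0.1001 in limma), and in limma without the trend (adjusted p of 0.0578). That for Chrna2 ended without KO replicate 2, WT replicate 1 or WT replicate 3 (9.27 to 10.6 points), and with both ends averaged (7.12). That for Olfr775 ended without KO replicate 2 or WT replicate 1 (8.69 and 10.6), and that for Defb6 without KO replicate 3 or WT replicate 2 (8.77 and 9.60) and with both ends averaged (4.84). The gene bodies that rose, of 5430401F13Rik (81.4% ± 2.93, 76.2% ± 3.35) and the prolactin family gene Prl2c5 (58.0% ± 3.37, 50.3% ± 4.75), had overlapping groups. The call for the first ended without KO replicate 1 or 3 or WT replicate 2 or 3 (3.66 to 5.22 points), and that for Prl2c5 without KO or WT replicates 2 or 3 (5.90 to 6.74).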

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

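The settings chosen after seeing the data are centring, scaling, limma without trend, the other gene ends, the median over tiles, valleys by the WT samples and classes by WT replicate 1. The global difference stayed negative in every setting run, at -4.89 points over medians and -6.20 on the logit scale. For the level classes under 10%, 10 to 50% and 80% and over, classes by the WT mean gave -1.10, -6.46 and -6.50 points, and classes by WT replicate 1 gave -1.26, -6.76 and -5.70. Tiles lower and higher numbered 87938 and 20 at 2 times the minimum difference, 200147 and 202 at an adjusted p under 0.01, 129769 and 18197 after centring and 128517 and 30656 after scaling. Gene ends lower and higher numbered 9172 and 53 with no minimum difference, 670 and 0 at 2 times it, 1559 and 150 after centring and 2218 and 133 after scaling. Higher gene ends numbered 5 at an adjusted p under 0.01, 5 with both ends averaged and 13 to 23 without one sample. Where 0 ends were higher, 101 were at an unadjusted p under 0.05 in limma. Gene bodies lower and higher numbered 2859 and 0 at 2 times the minimum, 2882 and 306 after centring and 2646 and 881 after scaling. Higher bodies numbered 11 with no minimum, 0 at an adjusted p under 0.01 (14 at an unadjusted p under 0.05 in limma) and 2 to 11 without one sample. Centring and scaling moved differences up, and no minimum is a looser limit; the cause of the other changes was not tested. The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at r = 0.00563, -0.00321 and 0.0110 across tiles, and with the replicate number as a block 316314 tiles, 3724 gene ends and 8191 gene bodies were lower and 1612, 9 and 1 higher. Tile counts without one sample ran from 243872 to 288387 lower and from 1300 to 1633 higher. For the 92 single results (regions, gene ends, gene bodies, distance classes), 1054 of 1109 values kept direction and call, 53 lost the call and 2 turned: the end of Stk31, at 3.12 points when chosen on the WT samples, and the body of Mrc1, at 0.182 after scaling. The settings on coverage, top-coverage sites, count tests, 500 bp tiles, CpG number, missing values, flanking bases and a chromosome filter were not run, since the table has only 1 kb levels on autosomes. Unknown depth limits how far a small difference at a single tile can be read.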

Other observations

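Set before their results were seen were the counts over splits of the samples and the tests of tiles outside genes and of starting level. All other tests here were set after. Gene families grouped by symbol were compared with lists matched in the same way, so not on distance to a valley. Olfactory receptor genes lost little: 25 of 1049 ends were called lower and 3 higher, with a median of -1.72 points against -4.06 for matched lists (adjusted permutation p = 0.00104). Vomeronasal receptor genes (2 of 255 ends lower, median -0.910, matched -3.95) and defensins (5 of 61 lower and 3 higher, median -0.608, matched -3.83) had the same adjusted p. Adjusted over the list alone, limma called 5 olfactory receptor ends lower and 0 higher, 0 vomeronasal ends in either direction, and 4 defensin ends lower and 2 higher. At an unadjusted p under 0.05 in limma, 113 olfactory ends were lower and 15 higher, and 23 vomeronasal ends lower and 11 higher. Over bodies, olfactory (median -1.55, matched -6.05) and vomeronasal receptor genes (-0.613, matched -7.12) had an adjusted permutation p of 0.00104, while defensins did not stand apart (-3.79, matched -5.84, 0.348). After centring or scaling the 3 medians at ends turned positive, from 3.17 to 4.28 points, while the median of all gene ends went to 0.233 and -2.05. At the other end, 22 of 36 clustered protocadherin genes, cell adhesion genes in tandem arrays, were lower over their bodies, with a median of -14.1 points (matched -10.5, adjusted permutation p = 0.0468). At their ends the family was split: 21 of 57 were lower (36.8%, against 18.7% of all gene ends) with a mean difference of -12.1 points, while the median was -3.97 (matched -5.78, adjusted permutation p = 0.0468), which centring turned to 0.925 and scaling to -0.0563. Genes of one array can overlap and share tiles, which was not checked. The counts and tests of this family may thus rest on fewer separate loci than members. The same limit holds for other families with neighbouring members, such as the Hox genes and the tandem receptor and defensin families. T-box genes had 4 of 12 ends lower with a median of -7.04 points (matched -2.96, 0.0156), and Polycomb genes 7 of 20 with -6.99 (matched -3.97, 0.0328). Over bodies the medians of T-box genes (-8.18, matched -8.77, adjusted permutation p = 0.845) and Polycomb genes (-6.56, matched -4.98, 0.180) did not stand apart from matched lists. Hox genes had 11 of 39 ends lower with a median of -2.92 (matched -1.56, adjusted permutation p = 0.0149), which centring turned to 1.97 and scaling left at -2.63. An end under 4.89% in WT turns positive on centring whatever its change. Over Hox bodies 6 of 13 were lower, and the median of -3.22 points was a smaller loss than in matched lists (-9.47, adjusted permutation p = 0.0243), which centring turned to 1.67 and scaling left at -2.74. Zinc finger Zfp genes did not stand apart at ends (-4.80, matched -5.07, adjusted permutation p = 0.500). Over bodies they had a smaller loss (-3.42, matched -3.96, 0.0130), which centring turned to 1.47 and scaling to 2.79. Forkhead, Sox, nuclear receptor, frizzled and ribosomal protein genes did not stand apart at ends or over bodies (adjusted permutation p from 0.0540 to 0.913).

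For the first pattern, the loss across the genome, one scaling factor between the groups is argued against, because 8.14% of tiles were still called after every sample was scaled to the same mean level. Fewer endothelial cells in the KO sorts would raise pan-endothelial gene ends, and their median difference was -5.36 points (SD between samples 0.351). This sign cannot decide the matter, since all gene ends fell by a median of -4.66 points, which can mask a rise. Centring left the list at -0.472 points, and it did not stand apart from matched lists (adjusted permutation p = 0.134). Such a shift would also lower markers of the cells gained. Mesenchymal ends fell beyond matched lists, while leukocyte and epithelial ends did not. Fewer endothelial cells in the KO sorts thus stay open. Fewer endothelial cells in the WT sorts would raise the ends of leukocyte, epithelial and mesenchymal markers, and their median difference over 73 genes was -7.82 points (SD 0.484). The loss across the genome bears on this sign too. After centring the leukocyte, epithelial and mesenchymal lists stayed negative, at -2.20, -2.02 and -5.56 points. The real grouping gave 317812 called tiles, 3735 gene ends and 8184 gene bodies, and the highest of the other splits gave 1, 0 and 0. The real grouping was 1 of 10 splits for each, and 10 splits are too few for a share under 0.05. Every other split mixes KO and WT samples, so the group difference adds to its spread. Its few calls thus do not measure false calls in the real grouping. The genotype, which the design names, stays among the open explanations and was not tested apart from the group comparison; what underlies the larger loss at mesenchymal markers stays open too.

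The second pattern is the larger loss beside valleys, where tiles at 1 to 3 kb had a median difference -7.25 points beyond that of tiles over 200 kb away. Overlap with genes is argued against, since the excess was -7.80 points among tiles outside genes (-8.98 to -7.33 over the 9 pairs of a KO and a WT sample). Regional gene density stays open, since tiles near and far from a valley were not matched on the genes around them. Starting level is argued against, since the excess was -7.88 points among tiles at 70 to 80% in WT replicate 1, with differences taken to the other WT samples. Averaging of a tile with the valley beside it is argued against for the outer part, since tiles at 6 to 10 kb still had an excess of -4.31 points; with valleys taken from the WT samples alone the mean difference was -12.1 points at 1 kb and -2.47 beyond 200 kb. A dependence of valley edges on Dnmt3a stays open and was not tested, and so does smoothing over longer windows, which no source used here describes.

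The third pattern is the small set of regions higher in KO. More unconverted cytosines in the KO libraries would raise tiles under 10%, and their median difference was -0.916 points. An even rise as large as the 10 points of a call is argued against, since these tiles averaged only 2.76% in KO. A smaller rise cannot be excluded, since the loss in this class, from 4.70% in WT, could mask it. Reads mostly shared with the ribosomal RNA sequence are argued against for the set as a whole. Over the 1548 other higher tiles the median r of deviations from the group means with the ribosomal region was 0.0558. Its 95% bootstrap interval over regions was 0.0211 to 0.101, and 6.40% of these tiles exceeded 0.8, against 5.78% of all tiles. Each r rests on 6 samples, whose spread the interval does not cover, so weaker sharing cannot be excluded. For the 9 other named regions, shared reads cannot be told apart from separate changes, since their median r of 0.659 lay between the limits set for either answer: Lars2 (0.997), the region on chromosome 6 (0.992), Atf2 (0.846) and Gphn (0.814) exceeded 0.8, and Oprk1 was at -0.295. A difference in the share or methylation of multicopy sequences between the groups could raise those 4 together, and copy number was not analysed here.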
